A study of Mus musculus with 6 samples.

How the data were processed

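The deposited counts are UMI counts per gene and barcode that the authors made before deposition: per the file headers Cell Ranger 3.0.2 wrote them, and the submitters' processing notes name the mm10 mouse genome and Seurat, without a role for the latter. Each deposited matrix held 31053 genes. Read alignment, barcode calling and any filter used by the authors were not repeated here. Groups and replicates were taken from the labels, and the counts of the 6 libraries fit whole-number UMIs with no normalization. Libraries of one age were not the same cells counted again, and the labels gave the ages the same replicate numbers without saying that a number marks shared animals, a litter or a day. The labels gave no day of collection and no handling per library, so neither was set apart from age.

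Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept: 7223, 10380, 8494, 9378, 7087 and 8020 cells in the libraries of E18.5, P2 and P7 in turn. Doublets were called per library with Scrublet as run in scanpy 1.11.5 and removed (3.23%, 3.25%, 4.79%, 4.63%, 4.26% and 4.08%), which left 6990, 10043, 8087, 8944, 6785 and 7693 cells. Counts were scaled per cell and logged, and 2000 variable genes, 40 principal components and 15 neighbours gave Leiden clusters at resolution 1 (igraph 0.11.9). No batch correction was used. Each cluster took the type whose markers stood out most in the share of its cells with a UMI, if at least 3 of them were seen in at least 0.2 of its cells. Peritubular and interstitial stromal clusters were joined as mesenchymal. Clusters made up mostly of doublet calls, with too few markers, or with median UMIs far below those of their libraries stayed unnamed. Germ clusters were split again at resolution 0.5 to set such low-UMI cells apart. Unnamed clusters held 178, 281, 334, 127, 84 and 486 kept cells, of which 7, 19, 154, 34, 38 and 242 lay in 3 clusters nearest to germ cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

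UMI counts were summed per library and cell class, since cells are not replicates, for the 8 classes with at least 20 cells in every library. Lymphoid cells and neutrophils were too few and entered the tests of shares alone. Genes passing filterByExpr (minimum count 10) were fitted with edgeR 4.0.16 in R 4.3.3: TMM factors, a quasi-likelihood fit with robust spread over all 6 libraries, and glmQLFTest for each step. P values were adjusted by Benjamini-Hochberg over the genes of a class and step, and genes were called at an adjusted p below 0.05. All p values for genes and shares in the text come from edgeR quasi-likelihood tests and those for lists from camera in limma 3.58.1. The contrast of P7 against E18.5 was fitted but is not described. Germ cell sums held the fewest UMIs in the E18.5 replicate 1 library (36 cells), so precision was lowest there. The germ cells per library were 36, 112, 81, 117, 602 and 899.

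Gene lists were fixed without sight of the values and tested with camera at a preset correlation of 0.01, adjusted over the lists of a class and step, and again with a correlation estimated from the data. With 2 libraries per age that estimate is imprecise, and it lay above the preset one for most lists. Members that served to name a class were left out of its lists. Lists for S phase, G2/M phase, imprinted genes, oxidative phosphorylation, glycolysis, ribosomal proteins, immediate early genes, heat shock, cholesterol biosynthesis, collagens, basement membrane and interferon response were run in every class, and the others in the classes they concern. "Adjusted over the list alone" means Benjamini-Hochberg over the members of the list.

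Cell classes were compared as shares with edgeR on the number of cells per class, with the log of all cells as offset, adjusted over the classes of a step. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs and are given without a test. The step of germ cells was set against that of Sertoli cells by the interaction of class and age in 1 edgeR model with the library as a block. It was called for 3705 of 17656 genes from E18.5 to P2 and 6310 from P2 to P7. The lists of that comparison other than S phase and G2/M were picked after the data were seen.

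Genes were named by a rule: called, mean of at least 50 CPM (counts scaled to the same library total) over the 6 sums, the libraries of one age all above those of the other, and a class mean of at least 0.1 of the highest class mean. Predicted genes, mitochondrial, haemoglobin and ribosomal protein genes were left out of that rule. From these came the 10 largest rises and falls for germ and Sertoli cells and 5 of each elsewhere. Up to 4 members of each list with the smallest p were named too, without that rule. Examples in the text were taken by preference from those called in every setting. Coordinates are from GENCODE vM21 (GRCm38). The comparisons, tests, markers, lists, naming rule and most alternatives were chosen before the data were examined, and 4 alternatives after.

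The tests were tested on simulated data made from the real sums. Of genes changed 4 times from E18.5 to P2, 86% were recovered in germ cells and 89.8% in Sertoli cells. Of those changed 2 times, 20.6% and 64.3% were recovered. In macrophages the share recovered at 4 times was 71.3%. False calls were 6 of 106 calls in germ cells and 19 of 170 in Sertoli cells over that step. From P2 to P7 they were 19 of 139 in endothelial cells and 2 of 102 in pericytes with vascular smooth muscle. The share of false calls thus passed the threshold on adjusted p in some classes and lay below it in others. A raised list was called, and 0 of 50 unchanged lists were, in each of 16 class and step pairs. The simulated genes varied independently of each other, so this does not show how often lists of genes that move together are called wrongly. Alternatives covered the normalization, DESeq2 1.42.0, no filter, only the libraries of the step, a replicate block, each library left out, doublets kept, a 20% mitochondrial limit, Leiden resolution 2 and equal depth of sums. Sequence reads, Seurat objects of the authors and splicing were not analysed here.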

Results

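Single-cell RNA profiles were collected from whole mouse testes at 3 ages around birth: embryonic day 18.5 (E18.5), postnatal day 2 (P2) and postnatal day 7 (P7). Each age had 2 biological replicates, and each replicate was 1 droplet library of unsorted testicular cells from C57BL/6 mice. The libraries of E18.5 held 7607 and 10852 barcodes, with median UMIs per barcode (counts of distinct captured RNA molecules) of 7850 and 6840. Those of P2 held 9177 and 9811 barcodes, with medians of 6873 and 7839. The libraries of P7 held 7827 and 8653 barcodes, with medians of 6158 and 9723. The question was how each cell type of the testis changed from late fetal life to P2 and from P2 to P7.

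Germ cells became a larger part of the recovered cells between P2 and P7, and Leydig, endothelial and neutrophil cells became a smaller part between E18.5 and P2. Germ cells made up 0.815% ± 0.424 (SD, n = 2) of the kept cells at E18.5, 1.155% ± 0.216 at P2 and 10.28% ± 1.99 at P7. Their share rose from P2 to P7 by 3.15 ± 0.396 (log2, SE; adjusted p = 7e-08, edgeR quasi-likelihood test). Left out of these shares were 3 unnamed clusters nearest to germ cells, with low UMIs or mostly doublet calls, which held 7, 19, 154, 34, 38 and 242 cells in the libraries of E18.5, P2 and P7 in turn. With them counted as germ cells, a choice made after seeing the data, the shares were 0.96% ± 0.49, 2.3% ± 0.86 and 12.13% ± 3.82. The later change was then 2.40 ± 0.386 (adjusted p = 7.37e-06), and the change from E18.5 to P2 was called too (1.24 ± 0.388, adjusted p = 0.00817). Leydig cells, which make androgens, went from 4.37% ± 0.129 at E18.5 to 1.62% ± 0.142 at P2, a log2 change of -1.43 ± 0.375 (adjusted p = 0.00319). Endothelial cells went from 3.32% ± 0.663 to 1.19% ± 0.206, a log2 change of -1.48 ± 0.38 (adjusted p = 0.00319). The neutrophil share changed by -1.67 from E18.5 to P2 (adjusted p = 0.00519) and by -2.95 from P2 to P7 (adjusted p = 0.00584), with 3 neutrophils in all at P7. Sertoli cells (36.0% ± 7.43, 50.6% ± 0.339 and 50.9% ± 6.13 over the 3 ages) and mesenchymal cells (48.6% ± 8.74, 40.3% ± 1.08 and 30.3% ± 12.2) were not called in either step. Macrophages, lymphoid cells, pericytes with vascular smooth muscle, and epithelial or mesothelial cells were not called either. The Leydig change was not called when barcodes with up to 20% mitochondrial UMIs were kept (-0.709) or without P2 replicate 1 (-1.34). From P2 to P7 the Leydig share was not called (0.378), and its direction turned with that limit of 20% (-0.497). Barcodes with at least 20 UMIs of Cyp11a1, Cyp17a1 and Hsd3b1 per 10000 were 1.82% ± 0.04 at P2 and 1.46% ± 0.56 at P7 within the limit of 10%. Without a limit they were 3.6% ± 0.57 and 1.76% ± 0.49. The endothelial and neutrophil changes at P2 were not called without P2 replicate 1 (-1.32 and -1.60), nor was the neutrophil change without E18.5 replicate 1 (-0.944). The later neutrophil change was not called without P7 replicate 1 (-2.64) or P7 replicate 2 (-3.40). With up to 20% mitochondrial UMIs the neutrophil cluster stayed without a name, as its median UMIs were 0.329 of those of its libraries against 0.334 here, so neither neutrophil change was tested there.

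**Figure D1:**
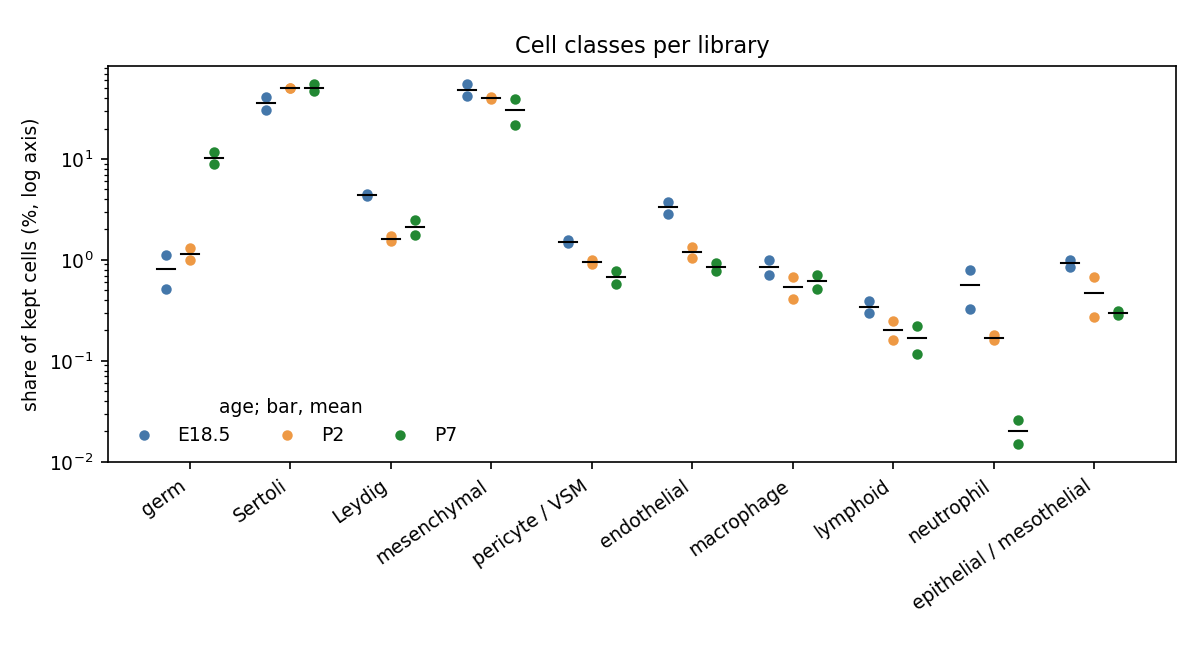
Share of kept cells (percent, log axis) per cell class, with 1 point per library (n = 2 per age) and a bar at each age's mean. The P7 germ points lie above those of E18.5 and P2, and the E18.5 Leydig and endothelial points lie above those of P2.

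**Figure D2:**
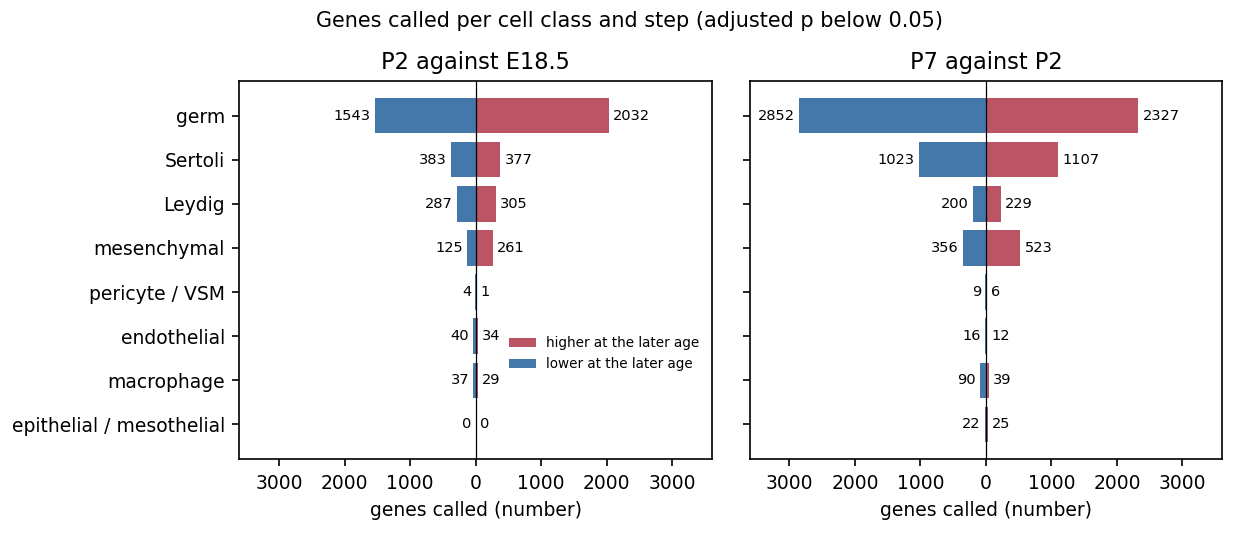
Genes called at adjusted p below 0.05 (number of genes) per cell class, drawn to the right where RNA was higher at the later age and to the left where it was lower. The germ bars are the longest in both steps.

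Between E18.5 and P2 germ cells took on RNA of the spermatogonial stem cell state and of DNA replication, and lost RNA of fetal genes for silencing transposons. At E18.5 male germ cells are arrested prospermatogonia, and they resume division after birth. Of 11707 genes tested, 2032 rose and 1543 fell. The 3575 calls compare with 1176 without E18.5 replicate 2 and 2380 without P2 replicate 2, and with 1988 when the sums of all libraries were thinned to the smallest. The cells came from different clusters at each age: 36 of 36 and 109 of 112 germ cells at E18.5 lay in a cluster led by Kdm1b, Utf1 and Spocd1, and 70 of 81 and 103 of 117 at P2 in one led by Afp, Tex12 and Etv4.

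In the spermatogonial stem cell list, 14 of 21 measured members rose and 2 fell, also when adjusted over the list alone, with a median log2 fold change of 1.97 (camera, adjusted p = 1.67e-09). Given an estimated correlation the adjusted p = 0.3. Gfra1 and Ret, the 2 parts of the receptor for the niche signal GDNF, rose by 4.59 ± 0.43 (log2, SE, n = 2 libraries per age) and 3.83 ± 0.35. Id4, a marker of stem cells among spermatogonia, rose by 3.36 ± 0.28. Etv4 (ENSMUSG00000017724, GRCm38 chromosome 11, 101769742 to 101785371), an ETS transcription factor, went from 6.82 ± 2.75 to 113 ± 7.56 CPM (SD; counts scaled to the same library total), a log2 change of 3.85 ± 0.30 (adjusted p = 7.22e-07). Its relative Etv5 rose by 3.85 ± 0.40. Stra8, which retinoic acid induces, rose by 3.75 ± 0.32, and the cyclin gene Ccnd1 by 3.04 ± 0.36. Other large rises were those of the transcription factor Dmrt1 (2.68 ± 0.27), of Slc9a3r1 (3.13 ± 0.25) and of Cirbp, the cold-inducible RNA-binding protein (3.32 ± 0.25). In the progenitor list 5 of 13 members rose (adjusted p = 0.0102), among them Nanos3 by 3.86, and adjusted p = 0.3 with an estimated correlation. That list was not called without E18.5 replicate 2 (adjusted p = 0.0668).

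Of the S phase list, 28 of 42 members rose and 14 were not called (32 rose and 2 fell adjusted over the list alone; median 1.06, adjusted p = 1.09e-09). Tested with an estimated correlation, its adjusted p = 0.173. Tipin, a protein of the replication fork, rose by 2.44 ± 0.22 and Uhrf1, which keeps DNA methylation through replication, by 2.87 ± 0.29. In the G2/M list 11 of 51 rose and 3 fell (median 0.35, adjusted p = 0.0201), with Cdk1 up by 2.06 and Hmgb2 by 1.52. Its adjusted p = 0.413 with an estimated correlation and 0.123 without E18.5 replicate 1. Of the cholesterol biosynthesis list 14 of 22 rose and 1 fell (17 and 1 adjusted over the list alone; median 1.08, adjusted p = 1.97e-05), with Acat2 up by 2.61 and Idi1 by 1.68. Its adjusted p = 0.289 with an estimated correlation. The oxidative phosphorylation list held 20 rises and 6 falls among 69 members (adjusted p = 0.0164, and adjusted p = 0.628 with an estimated correlation).

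The falls included the machinery that silences transposons in fetal germ cells. In the piRNA list 7 of 20 members fell and 2 rose (median -0.46, adjusted p = 0.0044), with Piwil4 at -2.52 ± 0.26, Tdrd9 at -2.20 ± 0.20 and Piwil2 at -1.40 ± 0.20. Its adjusted p = 0.289 with an estimated correlation. Spocd1, which links piRNAs to DNA methylation, changed by -3.60 ± 0.24. Dnmt3l, a cofactor of the enzymes that set new DNA methylation, went from 160 ± 15.3 to 29.9 ± 1.14 CPM, a change of -2.39 ± 0.22. The DNA methylation list as a whole was not called (2 of 16 rose, 5 fell, adjusted p = 0.0982). Kdm1b (ENSMUSG00000038080, chromosome 13, 47043499 to 47085279), a histone H3 lysine 4 demethylase, went from 424 ± 27.2 to 56.0 ± 4.60 CPM (-2.92 ± 0.18, adjusted p = 2.44e-07). Nme8 changed by -4.06 ± 0.29. Of the ribosomal protein list 22 of 50 fell and 3 rose (median -0.57, adjusted p = 9.39e-08, and adjusted p = 0.413 with an estimated correlation), though reads of these genes can be shared with pseudogenes. Collagens (2 of 20 fell, 1 rose, adjusted p = 0.00792) and basement membrane genes (5 of 16 fell, 1 rose, adjusted p = 0.0201) were called as lower. Their adjusted p = 0.413 and 0.3 with an estimated correlation, and the basement membrane list was not called without E18.5 replicate 1 or P2 replicate 2 (adjusted p up to 0.105). Markers of other cell types moved in the same direction: 2 of 4 peritubular markers (median -1.17), 2 of 5 endothelial (median -0.54) and 3 of 4 erythroid markers fell. Lists for meiotic entry (10 of 19 rose, 4 fell, adjusted p = 0.0762), differentiating spermatogonia (4 of 17 rose, 1 fell, 0.0987), pluripotency (3 of 19 rose, 4 fell, 0.465), imprinted genes (3 of 30 rose, 5 fell, 0.222), retinoid genes (2 of 10 fell, 0.222), interferon genes (4 of 12 fell, 0.115), heat shock genes (1 of 15 rose, 4 fell, 0.115), immediate early genes (2 of 24 rose, 3 fell, 0.503) and glycolysis (6 of 22 rose, 1 fell, 0.699) were not called.

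Germ cells turned from P2 to P7 towards dividing and differentiating spermatogonia, with lower RNA of stem cell, pluripotency and imprinted genes. Of 11707 genes tested, 2327 rose and 2852 fell, 5179 in all, against 3037 without P2 replicate 2 and 1510 with sums thinned to the smallest. At P7 the cells lay in a cluster led by Pou5f1, Zbtb16 and Egr4 (421 and 602 cells) and one led by Stra8 and Crabp1 (181 and 297 cells). Of the G2/M list 34 of 51 members rose (37 adjusted over the list alone; median 0.88, adjusted p = 9.58e-10). Hmmr, a spindle protein, rose by 2.65 ± 0.26 and Cdc20, an activator of anaphase, by 1.44 ± 0.20. Of the S phase list 26 of 42 rose and 1 fell (28 and 1 adjusted over the list alone; adjusted p = 1.23e-06). Both lists had adjusted p = 0.337 with an estimated correlation. In the progenitor list 7 of 13 rose and 2 fell (adjusted p = 0.0231, and 0.0517 without P2 replicate 2), with Neurog3, a mark of progenitors, up by 3.13 ± 0.56 and Sox3 by 1.78 ± 0.22. In the list of differentiating spermatogonia 7 of 17 rose and 4 fell (adjusted p = 0.0231), with Stra8 up by 1.77 ± 0.19 and Dmrtb1 by 3.20 ± 0.40. The adjusted p = 0.337 with an estimated correlation for both of these lists too.

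The stem cell list went the other way from its rise before P2: 14 of 21 members fell and 1 rose (15 and 1 adjusted over the list alone; median -1.08, adjusted p = 8.69e-04). Its adjusted p = 0.286 with an estimated correlation. Thy1, a surface antigen gene, changed by -3.75 ± 0.32, Etv5 by -1.42 ± 0.22 and Id4 by -1.13 ± 0.18, while Zbtb16, also a regulator of spermatogonial self-renewal, rose by 1.85 ± 0.20. Of the pluripotency list 9 of 19 fell and 4 rose (10 and 4 adjusted over the list alone; adjusted p = 0.0257, and adjusted p = 0.337 with an estimated correlation), with Sox2 at -3.12 ± 0.36, Utf1 at -2.28 ± 0.18 and Pou5f1 among the rises at 1.05 ± 0.16. Of the imprinted list 15 of 30 fell and 3 rose (16 and 3 adjusted over the list alone; median -0.81, adjusted p = 0.00237). Its adjusted p = 0.286 with an estimated correlation, and Grb10 changed by -2.46 ± 0.21, Slc38a4 by -2.45 ± 0.19 and Meg3 by -1.69 ± 0.18. Meg3 was also a leading gene of mesenchymal clusters, and markers of other cell types fell in germ cells over this step. A share of free RNA in the imprinted fall was not tested. Dnmt3l fell further, by 3.90 ± 0.27. The largest fall was that of the keratin gene Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027), from 110 ± 1.59 to 3.39 ± 0.342 CPM (-4.99 ± 0.20, adjusted p = 2.32e-10). Galk1 (2.53 ± 0.18), Srrt (2.53 ± 0.24) and Alad (2.23 ± 0.18) were among the largest rises.

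Less stable germ lists from P2 to P7 were oxidative phosphorylation (23 of 69 rose, 2 fell, adjusted p = 0.0115, and 0.471 without P7 replicate 2), immediate early genes (15 of 24 fell, 2 rose, 0.0115, and 0.122 without P7 replicate 2) and ribosomal proteins (12 of 50 rose, 1 fell, 0.0361, and up to 0.957 without P2 replicate 1 or P7 replicate 2). Collagens (8 of 20 fell, 1 rose, 0.0356) and basement membrane genes (8 of 16 fell, 0.0356) were not called without P2 replicate 1 or P7 replicate 2 (adjusted p up to 0.207 and 0.115). For these 5 lists the adjusted p = 0.703, 0.661, 0.703, 0.554 and 0.337 with an estimated correlation. Markers of other cell types fell beside them: 4 of 4 peritubular (median -2.41), 4 of 5 endothelial (median -2.12), 4 of 4 erythroid (median -3.21), 3 of 4 epithelial (median -1.52) and 2 of 7 Sertoli markers (median -0.65). Meiotic entry (6 of 19 rose, 5 fell, adjusted p = 0.577), piRNA genes (5 of 20 rose, 3 fell, 0.446), DNA methylation (6 of 16 rose, 4 fell, 0.616), cholesterol biosynthesis (4 of 22 rose, 7 fell, 0.351), glycolysis (6 of 22 rose, 7 fell, 0.506), heat shock (4 of 15 rose, 4 fell, 0.446), interferon (1 of 12 rose, 2 fell, 0.534) and retinoid genes (3 of 10 rose, 3 fell, 0.918) were not called.

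For most state genes the share of germ cells with a UMI followed the same course when every cell was thinned to 2000 UMIs, which removes differences in depth. Germ cells with a Gfra1 UMI were 0.9% at E18.5, 14.29% ± 0.52 (SD, n = 2) at P2 and 7.74% ± 1.51 at P7, and cells with an Id4 UMI were 1.35%, 23.64% and 10.54%. Cells with a Stra8 UMI were 1.35%, 18.92% ± 7.25 and 27.77% ± 0.42, and those with a Sox3 UMI 5.22%, 5.72% and 15.4%. Etv5 was seen in 0.9%, 12.57% and 3.33%, Nanos2 in 0%, 0.64% and 1.61%, and Neurog3 in 0%, 0% and 1.78%. Nanos2 thus did not fall with Gfra1, Id4 and Etv5 after P2. Dnmt3l went from 31.7% ± 5.34 to 5.98% and 0.33%, and Piwil4 from 17.71% to 3.42% and 1.64%. Kit (5.03%, 2.56% and 4.41%), Pou5f1 (25.97%, 23.84% and 22.4%) and Eomes (3.22%, 0% and 0.39%) showed no such course. Summed per library, Kit was called as higher at P7 than at P2 (1.05 ± 0.31, adjusted p = 0.0113). In Sertoli cells of the same libraries Gfra1 was seen in at most 0.06% of the cells of a library and Pou5f1 in at most 0.57%. Id4 was seen there in up to 2.26% and Etv5 in up to 2.34%, and the E18.5 germ shares of these 2 genes did not lie above those values. Whether Sertoli cells make this RNA themselves was not tested, so their shares are a reference and not a measured background. Before thinning, the median germ cell held 13578.5, 12082 and 19910 UMIs at the 3 ages and the median Sertoli cell 7932, 7988 and 9499.5. Without thinning, Gfra1 and Kit were seen together in 11 of 602 and 22 of 899 germ cells at P7, against 47.27 and 78.58 if they were independent. At P2 they were seen together in 6 of 81 and 10 of 117, against 3.53 and 7.69.

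**Figure D3:**
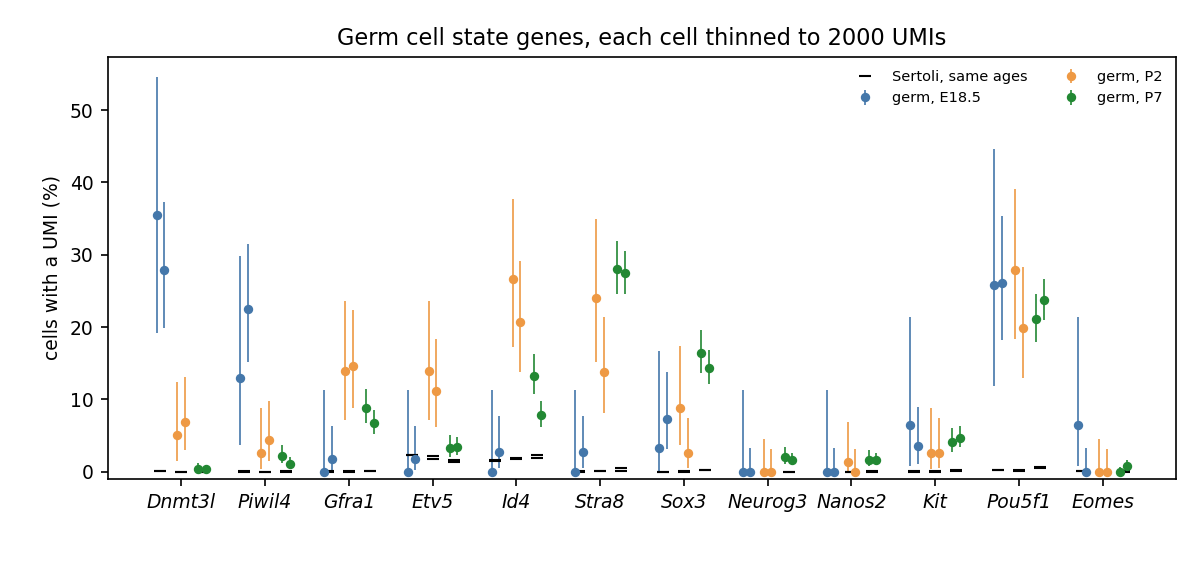
Share of cells with at least 1 UMI of each gene (percent of cells) after thinning each cell to 2000 UMIs, with 1 point per library for germ cells and its 95% Clopper-Pearson interval, and dashes for Sertoli cells of the same libraries. The Gfra1, Etv5 and Id4 shares are highest at P2, Stra8 and Sox3 at P7, and Dnmt3l and Piwil4 at E18.5.

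Cell cycle genes moved in opposite directions in germ and Sertoli cells after P2. In Sertoli cells, the somatic cells that nurse germ cells, 26 of 42 S phase genes fell from P2 to P7 (30 adjusted over the list alone; median -0.66, adjusted p = 5.8e-12), with Mcm4 at -0.84 ± 0.11. Of 52 G2/M genes 17 fell (32 adjusted over the list alone; median -0.54, adjusted p = 8.3e-09). With an estimated correlation the adjusted p = 0.25 and 0.462. The steps of germ and Sertoli cells were compared gene by gene in 1 model with the library as a block. From E18.5 to P2 the step was higher in germ cells for 50 of 94 cell cycle genes and lower for 2, and from P2 to P7 it was higher for 89 and lower for 0. Without the block the first count was 27 and the second 79. Thinned to 2000 UMIs, cells with a Mki67 UMI, a proliferation marker, went from 2.25% ± 3.18 to 8.31% ± 0.78 and 14.38% ± 0.35 of germ cells over the 3 ages. Thinned to 4000 UMIs the first 2 ages lay closer, at 8.12% ± 6.03 and 11.6% ± 0.01, and one E18.5 library (12.38%) lay above both of P2. At 2000 UMIs they went from 14.94% ± 5.83 to 13.12% ± 3.27 and 8.81% ± 0.71 of Sertoli cells. Summed per library, Mki67 was not called in germ cells (1.13 ± 0.41, adjusted p = 0.0553, and 0.65 ± 0.29, adjusted p = 0.0938) or in Sertoli cells (-0.19 ± 0.30, adjusted p = 0.817, and -0.66 ± 0.30, adjusted p = 0.185).

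**Figure D4:**
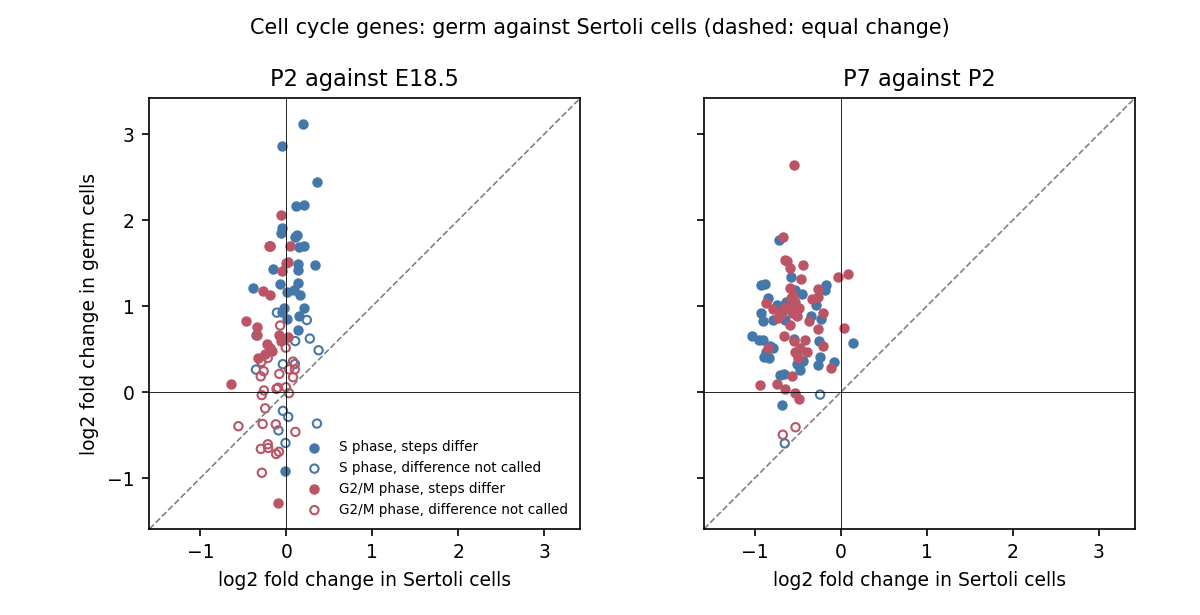
Log2 fold change of each S phase and G2/M gene in germ cells (vertical axis) against Sertoli cells (horizontal axis) in each step, filled where the steps differed (edgeR interaction, adjusted p below 0.05). From P2 to P7, 89 of 94 genes lie above the dashed line of equal change as called differences.

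From E18.5 to P2 Sertoli cells lowered genes of glycolysis and cholesterol synthesis, and the tight junction genes Cldn11 and Ocln rose. Of 14150 genes tested, 377 rose and 383 fell. The 760 calls dropped to 240 without E18.5 replicate 2, 142 without P2 replicate 1 and 88 without P2 replicate 2, and were 1710 with no filter on low counts. At E18.5 the cells lay mainly in clusters led by Ccl17 and Ptgds (1093 and 1924 cells) and by Ptgds, Pnmt and Ube2c (663 and 1532), and at P2 in one led by Edn1 and Hsd17b1 (2586 and 2456). Of the cholesterol biosynthesis list 17 of 24 fell (23 adjusted over the list alone; adjusted p = 4.04e-29), and of the glycolysis list 13 of 23 fell (16 adjusted over the list alone; median -0.61, adjusted p = 3.37e-17). Both lists had adjusted p = 0.0893 with an estimated correlation. Hexokinase Hk1 changed by -1.78 ± 0.15, lactate dehydrogenase Ldha (ENSMUSG00000063229, chromosome 7, 46841475 to 46855627) by -1.49 ± 0.12 and Pgk1 by -1.17 ± 0.11. Vegfa, an angiogenic factor that low oxygen induces, changed by -2.09 ± 0.18. Of the interferon list 4 of 21 fell and 1 rose (12 and 2 adjusted over the list alone; median -0.51, adjusted p = 9.19e-06, and adjusted p = 0.11 with an estimated correlation), with Bst2 at -1.99 ± 0.13. The claudin gene Cldn11 (ENSMUSG00000037625, chromosome 3, 31149920 to 31164324), part of the tight junctions between Sertoli cells, went from 15.7 ± 0.163 to 71.7 ± 8.70 CPM (2.19 ± 0.14, adjusted p = 6.74e-04). Ocln, another tight junction gene, rose by 1.60 ± 0.14, Nr0b1 by 1.65 ± 0.12, Nfix by 1.54 ± 0.14 and Rdh10, an enzyme of retinoic acid synthesis, by 2.09 ± 0.20. The chemokine gene Ccl17 went from 784 ± 35.3 to 225 ± 19.9 CPM (-1.80 ± 0.12, adjusted p = 7.96e-04).

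In the junction list of Sertoli cells 3 of 23 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.0337, adjusted p = 0.309 with an estimated correlation, and 0.111 without E18.5 replicate 1). Niche ligands (2 of 28 fell, adjusted p = 0.00108) were not called without E18.5 replicate 1 or P2 replicate 2 (adjusted p up to 0.119), and heat shock genes (1 of 16 fell, 0.0133) without E18.5 replicate 1 or P2 replicate 1 (up to 0.413). The G2/M list (0 of 52 genes called by edgeR, 0.0306) was not called without E18.5 replicate 2 or P2 replicate 1 (up to 0.882). For these 3 lists the adjusted p = 0.61, 0.712 and 0.919 with an estimated correlation. Lists of immature Sertoli cells (2 of 21 rose, 4 fell, adjusted p = 0.5) and of Sertoli maturation (3 of 29 rose, 3 fell, 0.737) were not called at this step. Beside these changes 2 of 4 Leydig markers fell (median -1.56).

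From P2 to P7 Sertoli cells gained maturation genes and lost immature ones while their cell cycle genes fell. Of 14150 genes tested, 1107 rose and 1023 fell, 2130 in all, against 564 without P2 replicate 1, 547 without P2 replicate 2 and 995 without P7 replicate 1. The cells at P7 lay in clusters led by Wfdc10 and Rhox8 (1585 and 2280 cells), Shisa8 and Cidea (867 and 936) and Wfdc10 and Cldn11 (668 and 1013). Of the maturation list 7 of 29 members rose (13 rose and 4 fell adjusted over the list alone; median 0.26, adjusted p = 1.42e-05). Cldn11 rose by 2.48 ± 0.14, the transcription factor Gata1 by 2.33 ± 0.23 and the lactate transporter Slc16a3 by 2.14 ± 0.18. From E18.5 to P2 Slc16a3 had changed by -1.53 ± 0.18, so its means were 64.8, 22.4 and 98.8 CPM over the 3 ages. Of the immature list 7 of 21 fell and 2 rose (10 and 2 adjusted over the list alone; median -0.87, adjusted p = 3.63e-07), with the adhesion molecule Ncam1 at -3.15 ± 0.15, prostaglandin synthase Ptgds at -2.80 ± 0.20 and the keratin Krt8 at -1.64 ± 0.11. Of the retinoid list 4 of 18 rose (adjusted p = 0.00175). Given an estimated correlation the adjusted p = 0.25 for each of these 3 lists. Basp1 had the largest rise, from 55.2 ± 0.399 to 639 ± 103 CPM (3.53 ± 0.15, adjusted p = 4.83e-05), and Shisa8 rose by 2.62 ± 0.13. Ccl17 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036) fell further to 5.14 ± 0.0308 CPM (-5.45 ± 0.15, adjusted p = 5.52e-06), and Pnmt changed by -4.53 ± 0.20.

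Other Sertoli lists called as lower at P7 were imprinted genes (6 of 32 fell, adjusted p = 0.00179), with Plagl1 at -2.07 ± 0.21, and collagens (6 of 29 fell, 1 rose, 2.07e-04), with Fbln2 at -1.27 ± 0.13. Ribosomal proteins (4 of 50 fell, 3.83e-08), immediate early genes (13 of 25 fell, 2.08e-09) and heat shock genes (2 of 16 fell, 1 rose, 0.0138, and 0.176 without P2 replicate 2) were called as lower too. For these 5 lists the adjusted p = 0.412, 0.412, 0.511, 0.412 and 0.47 with an estimated correlation. Junction genes (4 of 23 rose, 1 fell, adjusted p = 0.0576), glycolysis (4 of 23 rose, 1 fell, 0.0585) and niche ligands (2 of 28 rose, 4 fell, 0.281) were not called. Of 7 germ markers 4 rose in the Sertoli sums (median 1.55), and 2 of 4 Leydig markers fell (median -1.15).

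In the Leydig cells kept within the limit on mitochondrial UMIs, the cholesterol pathway fell steeply between E18.5 and P2. More genes of the fetal Leydig list fell than rose, and more of the adult list rose than fell. Of 10163 genes tested, 305 rose and 287 fell. The 592 calls were 302 and 176 without E18.5 replicates 1 and 2 in turn, 281 and 273 without P2 replicates 1 and 2, and 1146 with up to 20% mitochondrial UMIs. The class drew on different clusters. One led by Cyp11a1 and Cyp17a1 held 291 and 439 cells at E18.5, 91 and 126 at P2 and 16 and 49 at P7. One with Insl3 among its leading genes held 8 and 9, 32 and 28, and 103 and 140. Cells with at least 20 UMIs of Cyp11a1, Cyp17a1 and Hsd3b1 per 10000 made up less of the class with age. They were 99.7% and 98.9% at E18.5, 87.8% and 92.9% at P2 and 58.8% and 73.0% at P7. Of all barcodes at that level, the limit on mitochondrial UMIs left out 25.5% and 16.5% at E18.5 and 57.4% and 44.0% at P2. The lists were not tested again with a higher limit. Selection of cells by the limit is thus not set apart from a change within Leydig cells in the lists below. Of the cholesterol biosynthesis list 21 of 24 fell (22 adjusted over the list alone; median -2.14, adjusted p = 1.24e-86), and this call held with an estimated correlation (adjusted p = 0.039). Ebp (ENSMUSG00000031168, chromosome X, 8185329 to 8193512), a sterol isomerase, went from 406 ± 59.8 to 50.1 ± 5.18 CPM (-3.00 ± 0.22, adjusted p = 4.45e-05), Mvd changed by -3.07 ± 0.25 and Dhcr7 by -2.49 ± 0.19. Of the glycolysis list 11 of 20 fell and 1 rose (13 and 2 adjusted over the list alone; median -0.88, adjusted p = 7.59e-13, and adjusted p = 0.0778 with an estimated correlation), with Eno1 at -2.09 ± 0.22. Of the fetal Leydig list 5 of 13 fell and 2 rose (7 and 3 adjusted over the list alone; median -0.62, adjusted p = 6.13e-05), with the neuropeptide gene Npy at -5.12 ± 0.47 and the renin gene Ren1 at -2.34 ± 0.27. Of the adult Leydig list 4 of 11 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 4.03e-04), among them Vcam1, a cell adhesion gene, by 4.60 ± 0.48, Akr1c14 by 3.32 ± 0.49 and the steroid reductase Srd5a1 by 2.50 ± 0.28. Tested with an estimated correlation, the adjusted p = 0.155 for the fetal and 0.263 for the adult list. Of the steroidogenesis list 4 of 16 fell and 2 rose (adjusted p = 0.00413, adjusted p = 0.438 with an estimated correlation), with the luteinizing hormone receptor gene Lhcgr at -1.45 ± 0.16.

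Also called in Leydig cells at P2 were lower G2/M genes (8 of 50 fell, adjusted p = 7.48e-10) and higher basement membrane genes (6 of 15 rose, 1 fell, 8.44e-05), with adjusted p = 0.343 and 0.285 with an estimated correlation. Immediate early genes, which tissue dissociation can induce, were higher as a list (1 of 25 rose, 5 adjusted over the list alone; median 0.46, adjusted p = 1.94e-04), and so were ribosomal proteins (0 of 50 called by edgeR, 2.75e-04). Their adjusted p = 0.466 and 0.563 with an estimated correlation. Lower oxidative phosphorylation (0 of 69 called by edgeR, adjusted p = 0.00157), higher collagens (5 of 22 rose, 0.0212) and lower interferon genes (3 of 16 fell, 0.0227) were called less stably. Without P2 replicate 1 or an E18.5 library these 3 calls were lost (adjusted p up to 0.0593, 0.526 and 0.229), and with an estimated correlation the adjusted p = 0.629, 0.579 and 0.438. The class also held more RNA of other types at P2: 3 of 7 Sertoli markers (median 1.05) and 2 of 2 Schwann cell markers (median 2.11) rose, and 2 of 4 adrenal-like markers fell (median -1.93). In the later step 229 genes rose and 200 fell, 429 in all, but 44 without P2 replicate 2 and 1156 with up to 20% mitochondrial UMIs. G2/M genes were higher in this step (7 of 50 rose, 12 rose and 1 fell adjusted over the list alone; median 0.66, adjusted p = 4.02e-08, and adjusted p = 0.302 with an estimated correlation). Their genes depended on the filters: with up to 20% mitochondrial UMIs Cdc20 went from 1.59 to -0.37 and Mki67 from 1.66 to 0.35, and with doublet calls kept they were at 0.64 and 0.81, not called. Basement membrane genes rose (8 of 15, adjusted p = 7.32e-10), with Col4a2 up by 1.51 ± 0.18, and so did collagens (6 of 22 rose, 1 fell, 4.02e-08), beside 2 of 6 stromal markers (median 0.73). Immediate early genes fell (9 of 25, adjusted p = 8.53e-18), with Egr2 at -2.59 ± 0.29. The fetal Leydig list fell again (3 of 13, adjusted p = 0.00249), with Gramd1b at -1.40 ± 0.17, as did niche ligands (4 of 24 fell, 1 rose, 0.00976), with the activin gene Inhba at -2.21 ± 0.28. With an estimated correlation the adjusted p = 0.257 for each of these lists except the collagens, which had adjusted p = 0.302. Less stable were lower oxidative phosphorylation (0 of 69 called by edgeR, adjusted p = 7.93e-07, and 0.15 without P7 replicate 1) and lower cholesterol biosynthesis (3 of 24 fell, 0.0201, and up to 0.172 without P2 replicate 1 or P7 replicate 2), with adjusted p = 0.551 and 0.488 with an estimated correlation. Igfbp6 rose by 2.79 ± 0.23, Aqp2 by 2.60 ± 0.23 and Cdkn1c changed by -1.82 ± 0.20. Steroidogenesis (0 of 16 genes called by edgeR, adjusted p = 0.806) and the adult list (2 of 11 rose, 2 fell, 0.806) were not called at this step.

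Mesenchymal cells, which here include peritubular and interstitial stromal cells, raised contractile genes over both steps. From E18.5 to P2, 261 of 14275 genes rose and 125 fell. The 386 calls were 146 without E18.5 replicate 2, 80 without P2 replicate 1, 94 without P2 replicate 2 and 1308 with no filter on low counts. In the step to P7, 523 rose and 356 fell, 879 in all, with 204 and 233 without P2 replicates 1 and 2 275 without P7 replicate 1 and 2034 with no filter. The largest clusters were led by Sostdc1 and Cxcl12 at E18.5 (2190 and 2015 cells), by Dcn, Inhba and Meg3 at P2 (1770 and 1806) and by Clec3b and Igfbp6 at P7 (1466 and 910), with one led by Acta2 and Tagln beside it at P7 (837 and 493). Clec3b (ENSMUSG00000025784, chromosome 9, 123150946 to 123157432), which encodes tetranectin, went from 1.75 ± 0.535 to 22.1 ± 4.83 and 415 ± 52.6 CPM over the 3 ages, changes of 3.64 ± 0.25 (adjusted p = 0.00207) and 4.24 ± 0.23 (adjusted p = 6.32e-04). At P2 Cyp26b1, an enzyme that degrades retinoic acid, rose by 2.33 ± 0.17, Postn by 3.04 ± 0.24, Mfap5 by 2.29 ± 0.18 and Cav1 by 1.51 ± 0.13, while Sostdc1 changed by -1.53 ± 0.16 and the receptor gene Ngfr by -1.39 ± 0.11. Of the smooth muscle list 6 of 24 rose at P2 (10 adjusted over the list alone; median 0.41, adjusted p = 3.32e-10) and 10 of 24 at P7 (16 rose and 1 fell adjusted over the list alone; median 0.63, adjusted p = 8.43e-15). Given an estimated correlation the adjusted p = 0.427 and 0.199. The integrin gene Itga8 rose by 2.83 ± 0.24 at P7. Without the clusters led by Acta2 or Myh11, a choice made after seeing the data, Tagln was at -1.44 from P2 to P7. The cluster led by Acta2 and Tagln held 9 and 15 cells at P2. Leaving it out thus took contractile cells mainly from P7, so this value does not show where the rise lay.

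Cell cycle genes fell in mesenchymal cells from P2 to P7, with 13 of 42 S phase genes (30 adjusted over the list alone; median -0.65, adjusted p = 8.95e-16) and 11 of 52 G2/M genes (34 adjusted over the list alone; median -0.61, adjusted p = 8.43e-15). Both had adjusted p = 0.321 with an estimated correlation, and Dtl changed by -1.10 ± 0.15. Basement membrane genes rose (7 of 20, 14 adjusted over the list alone; adjusted p = 2.38e-08, and adjusted p = 0.199 with an estimated correlation). At P2 collagens (5 of 29 rose, 2 fell, adjusted p = 0.00263) and interferon genes (4 of 23 fell, 5.46e-05) were called, and G2/M genes were lower (1 of 52 fell, 2.96e-11). Tested with an estimated correlation, the adjusted p = 0.427, 0.427 and 0.628 for these 3 lists. The list of stromal and Leydig progenitors was called in neither step (3 of 31 rose and 2 fell, adjusted p = 0.715, then 3 rose and 4 fell, 0.472). Of the latter Ly6a, a stem cell antigen gene, rose by 6.03 ± 0.42. Of 4 Leydig markers 2 fell in each step (medians -1.23 and -1.86).

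In endothelial cells G2/M and glycolysis genes were lower as lists at P2, and tip cell and imprinted genes were lower as lists at P7. Up to P2, 34 of 8733 genes rose and 40 fell. The 74 calls were 32 without E18.5 replicate 2, 38 without P2 replicate 1, 150 without P7 replicate 1 and 123 without P7 replicate 2. Gsn rose by 2.35 ± 0.23 and Nxpe2 by 2.38 ± 0.26, and the matrix gene Fbln2 changed by -2.05 ± 0.22. G2/M genes were lower (1 of 51 fell, 20 adjusted over the list alone; median -0.70, adjusted p = 2.09e-24), and so was glycolysis (4 of 17 fell, 10 adjusted over the list alone; median -0.61, adjusted p = 4.97e-11). Their adjusted p = 0.256 and 0.126 with an estimated correlation. Between P2 and P7, 12 genes rose and 16 fell, with Fbln2 back up by 1.28 ± 0.24 (adjusted p = 0.0369). The 28 calls were 10 without P2 replicate 1 and 61 without P7 replicate 2. H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143), an imprinted long noncoding RNA, went from 288 ± 35.4 to 87.6 ± 4.17 and 4.98 ± 0.676 CPM over the 3 ages, changes of -1.72 ± 0.19 and -4.14 ± 0.35 (adjusted p = 4.44e-04 and 1.07e-04). Of the imprinted list 3 of 24 fell at P7 (adjusted p = 3.23e-07), and the tip cell list was lower (0 of 18 genes called by edgeR, 5 fell adjusted over the list alone; median -0.48, adjusted p = 3.7e-05). With an estimated correlation the adjusted p = 0.135 and 0.163. From E18.5 to P2 the imprinted list was called as lower as well (2 of 24 fell, adjusted p = 0.00295, and up to 0.0828 without E18.5 replicate 2 or P2 replicate 2). The tip cell list was called as higher over that step (2 of 18 rose, 1 fell, adjusted p = 0.0192, and up to 0.366 without P2 replicate 1 or either E18.5 replicate). Their adjusted p = 0.375 and 0.413 with an estimated correlation. The list of mature capillary endothelium was called in neither step (2 of 17 rose and 1 fell, adjusted p = 0.679, then 0 called, 0.223).

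Macrophages took on genes of resident tissue macrophages over both steps. Up to P2, 29 of 5575 genes rose and 37 fell. The 66 calls were 35 without E18.5 replicate 2, 43 and 29 without P2 replicates 1 and 2, and 200 and 187 without P7 replicates 1 and 2. Between P2 and P7, 39 rose and 90 fell. These 129 calls were 56 without P2 replicate 2, and 293 and 294 without P7 replicates 1 and 2. At P2 the lipase gene Lpl rose by 3.01 ± 0.32, Hmox1, which breaks down haem, by 2.89 ± 0.31 and the fatty acid receptor gene Cd36 by 2.06 ± 0.32. Of the resident list 2 of 13 rose at P2 (6 rose and 1 fell adjusted over the list alone; adjusted p = 3.49e-05) and 4 of 13 at P7 (6 adjusted over the list alone; median 0.86, adjusted p = 8.12e-12). At P7 Cbr2 rose by 3.96 ± 0.33, Folr2 by 2.81 ± 0.37 and Pf4 by 1.81 ± 0.25. The list fixed for MHC class II also held genes outside antigen presentation, among them the monocyte receptor gene Ccr2. Of this list 2 of 12 fell (6 adjusted over the list alone; median -1.49, adjusted p = 4.28e-09): Ccr2 at -2.76 ± 0.36 and Cd74, the MHC class II invariant chain, at -1.61 ± 0.33. Given an estimated correlation the adjusted p = 0.333 and 0.141 for the resident list and 0.139 for the list of MHC class II. Inflammatory genes (3 of 15 fell, adjusted p = 0.00307, adjusted p = 0.141 with an estimated correlation, and 0.0661 without P7 replicate 1) included Ccl4 at -2.19 ± 0.32. Ly6c2, a monocyte antigen gene, changed by -4.18 ± 0.32, and 2 of 3 neutrophil markers fell, with S100a8 at -6.93 ± 0.39. G2/M genes were lower at P2 (9 of 34 fell, 23 adjusted over the list alone; adjusted p = 2.76e-28) and higher at P7 (5 of 34 rose, 12 rose and 1 fell adjusted over the list alone; adjusted p = 8.09e-11). Tested with an estimated correlation, the adjusted p = 0.303 and 0.251.

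Pericytes with vascular smooth muscle and epithelial or mesothelial cells gave few calls. In the pericyte class 1 of 6688 genes rose and 4 fell from E18.5 to P2. Those 5 calls were 19 without E18.5 replicate 1, 12 without P2 replicate 2, and 54 and 50 without P7 replicates 1 and 2. Of these the matrix gene Reln changed by -2.32 ± 0.32 and H19 by -1.57 ± 0.20. Between P2 and P7, 6 rose and 9 fell. Those 15 calls were 51 and 45 without E18.5 replicates 1 and 2, 27 without P2 replicate 1, and 81 and 146 without P7 replicates 1 and 2. G2/M genes were lower at P7 (3 of 49 fell, 34 adjusted over the list alone; median -1.33, adjusted p = 2.2e-32) and contractile genes higher (0 of 22 called by edgeR, 5 rose adjusted over the list alone; adjusted p = 2.05e-07). With an estimated correlation the adjusted p = 0.166 and 0.106. In epithelial or mesothelial cells edgeR called 0 of 6956 genes from E18.5 to P2, where 250 had an unadjusted p below 0.05 and DESeq2 also called 0. That count was 5 and 3 without E18.5 replicates 1 and 2, and 15 and 4 without P2 replicates 1 and 2. In their later step 25 rose and 22 fell. Those 47 calls were 90 and 89 without E18.5 replicates 1 and 2, 109 without P2 replicate 1, and 10 and 110 without P7 replicates 1 and 2. The cell cycle inhibitor gene Cdkn1c changed by -2.47 ± 0.32, the matrix gene Mfap2 by -3.14 ± 0.40 and the growth factor gene Hbegf by -3.10 ± 0.39 at P7.

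Some lists moved together across classes. From E18.5 to P2 glycolysis was called as lower in 6 of 8 classes, with medians of -0.88 in Leydig, -0.61 in Sertoli, -0.61 in endothelial, -0.56 in epithelial or mesothelial, -0.44 in pericytes with vascular smooth muscle and -0.21 in mesenchymal cells. The mesenchymal call was lost without E18.5 replicate 1 (adjusted p = 0.132). Over the same step cholesterol biosynthesis was called as lower in all 7 somatic classes tested and as higher in germ cells, and the mesenchymal call was lost without E18.5 replicate 1 (adjusted p = 0.643). Leydig markers had lower medians in other classes over that step: -1.56 in Sertoli, -1.23 in mesenchymal, -1.98 in endothelial and -2.68 in epithelial cells. Pericytes had -2.72, and germ cells, where the cholesterol list rose, had -1.93. Free RNA of Leydig cells was not tested as a source of the shared cholesterol fall. Gene by gene, the step of germ cells was above that of Sertoli cells for 20 of 24 cholesterol genes, and for 14 of 24 glycolysis genes with 1 below. These 2 lists were picked for that test after their values were seen. From P2 to P7 immediate early genes were called as lower in all 8 classes, with medians from -1.09 in macrophages to -0.51 in epithelial or mesothelial cells. Tissue dissociation can induce these genes, and a difference in handling over this step was not tested and cannot be set apart from age. Heat shock genes were called as lower in the 7 somatic classes over that step, but not without P2 replicate 2 in Sertoli (adjusted p = 0.176), Leydig (0.0521) and epithelial or mesothelial cells (0.799). The call of immediate early genes was lost in germ cells without P7 replicate 2 (adjusted p = 0.122) and in epithelial or mesothelial cells without P2 replicate 1 (adjusted p = 0.439). Imprinted genes were called over that step as lower in germ, Sertoli, mesenchymal, endothelial, epithelial or mesothelial cells and pericytes, and as higher in Leydig cells (4 of 28 rose, 1 fell, median 0.41, adjusted p = 0.0212). The mesenchymal call was lost without P7 replicate 1 (adjusted p = 0.0847), and the Leydig call without P2 replicate 2, P7 replicate 1 or P7 replicate 2 (adjusted p up to 0.186). Given an estimated correlation 1 of these calls, cholesterol biosynthesis in Leydig cells, held (adjusted p = 0.039).

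**Figure D5:**
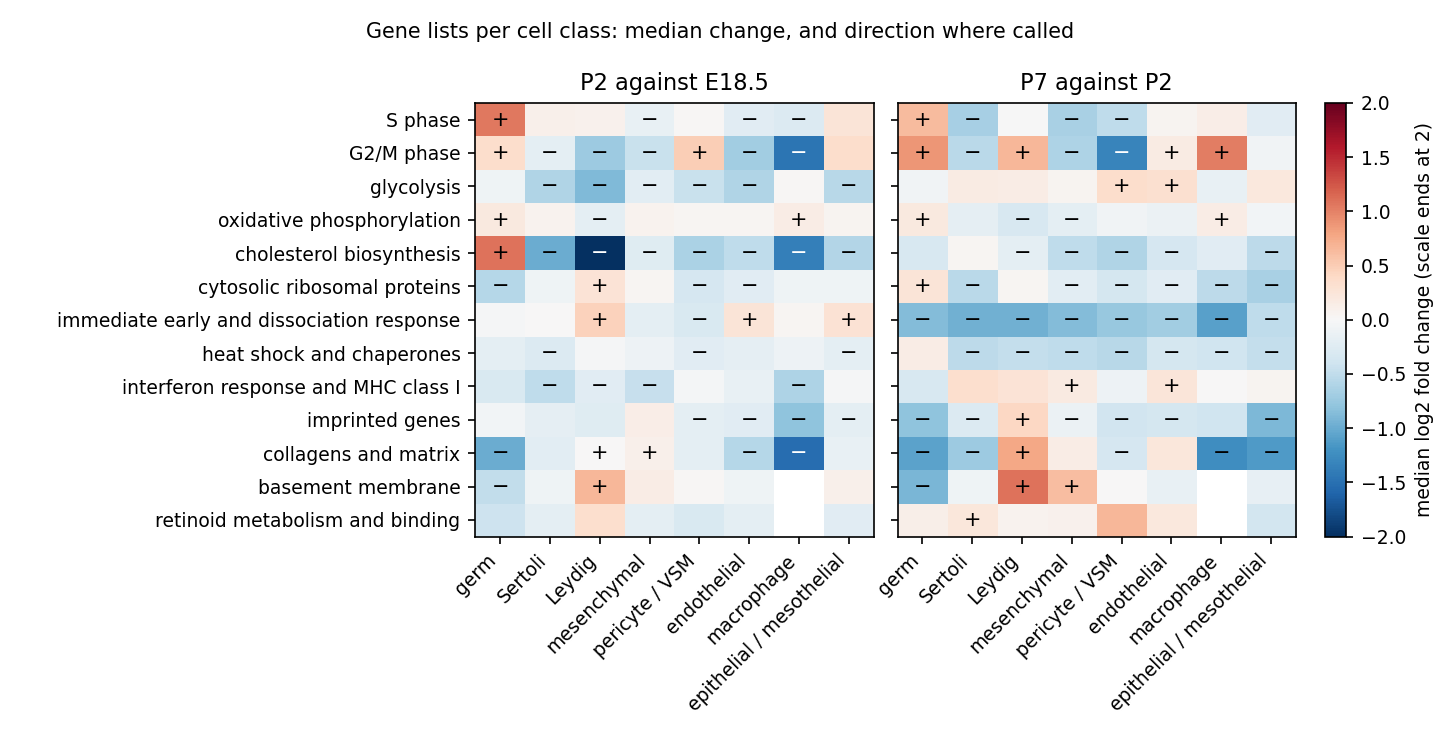
Median log2 fold change (colour) of 13 fixed gene lists per cell class and step, with plus or minus where camera called the list as higher or lower at adjusted p below 0.05. From E18.5 to P2, cholesterol biosynthesis was lower in the 7 somatic classes (median -2.14 in Leydig cells) and higher in germ cells (median 1.08).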

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

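Of the 7 tests of technical explanations, the 2 that matched numbers of cells were set out before their result was seen, and the other 5 were chosen after. Results were singled out where a test of germ against Sertoli cells differed, or where a signal lay in cells the comparisons did not use.

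More genes were called in germ than in Sertoli cells, 3575 against 760 from E18.5 to P2 and 5179 against 2130 from P2 to P7. Unequal numbers of cells are argued against: Sertoli cells drawn to match the germ cells in number gave means of 47.8 and 429.4 calls. These draws did not make UMIs equal, as Sertoli cells held fewer per cell in every library (9292 against 12026 in E18.5 replicate 1). Full Sertoli sums held more UMIs than germ sums in every library, yet gave fewer calls. Germ sums thinned to the smallest total, at most 432919 UMIs each, gave 1988 and 1510 calls. The first exceeded 760, though full Sertoli sums held at least 19997373 UMIs. The second lay below 2130, from Sertoli sums that were far larger. The Sertoli draws held more UMIs than the thinned germ sums at P2 and P7. The smallest of these had 81 cells, at a class mean of 7825 UMIs per cell. From P2 to P7 the draws gave at most 515 calls, against 1510. These values argue against unequal UMIs as the source of the excess. For free RNA of other cell types, 3429 and then 4790 germ calls stayed among genes at 0.1 of the highest class mean or above. Most calls were thus not on genes found mainly in other classes. Genes that germ cells share with other classes pass that level whatever moved them, so free RNA of shared genes was not tested. Markers of other types fell in germ cells, from P2 to P7 with medians of -2.41 (peritubular), -2.12 (endothelial) and -3.21 (erythroid). The step itself differed between germ and Sertoli cells for 3705 and then 6310 genes, and was higher in germ cells for 50 and then 89 of 94 cell cycle genes. A change of cell state at birth is a candidate explanation that stays open, as the labels give no day of collection or handling to set apart from age.

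The Leydig share was lower at P2 than at E18.5. Of barcodes rich in Leydig marker UMIs, which the comparisons left out above the limit on mitochondrial UMIs, 25.5% and 16.5% lay above it at E18.5, 57.4% and 44.0% at P2 and 29.9% and 16.4% at P7. Without a limit the log2 ratio of mean shares was -0.72, against -1.39 within it, so removal by the limit could account for part of the change. Damage of Leydig cells in dissociation and a true loss cannot be told apart with these tables.

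Glycolysis genes were called as lower at P2 than at E18.5 in 6 somatic classes, but in 0 of them with an estimated correlation, and in mesenchymal cells not without E18.5 replicate 1 (adjusted p = 0.132). Free RNA shared by a library is argued against by germ cells, where the list had a median of -0.092, but for the larger falls alone. Mesenchymal cells lay near germ cells, with a median of -0.206. Germ cells held more UMIs than Sertoli cells (medians of 13578.5 against 7932 at E18.5), which would dilute free RNA. Leydig cells, with the largest fall, held 15027. A dissociation response that differed between ages stays open: the immediate early list was called in 4 of the 6 classes, as higher in Leydig (median 0.462), endothelial (0.25) and epithelial or mesothelial cells (0.282) and as lower in pericytes (-0.298). With an estimated correlation 0 of these calls held, and the last 3 were each lost without some single libraries (adjusted p up to 0.159, 0.812 and 0.688), so whether the list differed, and in which direction, is not settled. A response to the oxygen of air after birth is another candidate explanation, as is handling that differed between collections, and these 2 were not tested.

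Clusters without a name held 2.55% and 2.8% of kept cells at E18.5, 4.13% and 1.42% at P2, and 1.24% and 6.32% at P7. Of these clusters 3 were nearest to germ cells, with 154 cells in P2 replicate 1, against 81 named germ cells, and 242 in P7 replicate 2. Counted as germ cells, they moved the log2 change of the germ share from 3.15 to 2.40 for P7 against P2.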

How the results depend on the processing

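Of the alternatives 4 were chosen after the data were seen (mesenchymal cells without the clusters led by Acta2 or Myh11, germ cells with at least 5000 UMIs, genes at 0.1 of the highest class mean or above, and unnamed clusters nearest to germ cells counted as germ cells) and the others before; the cause of a change was not tested. A left-out library leaves 1 library at its age, assumed to vary like the others. In each pair below the value for P2 against E18.5 comes before that for P7 against P2. Leaving out each library in turn, genes called ranged over 1176 to 4017 and 3037 to 5443 in germ cells, 88 to 667 and 547 to 1798 in Sertoli, 176 to 862 and 44 to 510 in Leydig, 80 to 293 and 204 to 874 in mesenchymal, 32 to 150 and 10 to 61 in endothelial cells, 29 to 200 and 56 to 294 in macrophages, 4 to 54 and 13 to 146 in pericytes, and 0 to 15 and 10 to 110 in epithelial cells. Lists called at P2 ranged over 4 to 9 in Sertoli, 4 to 8 in epithelial and 4 to 8 in mesenchymal cells, and at P7 over 7 to 12 in germ cells. Classes with a changed share ranged over 0 to 4 and 1 to 2. The log2 change of share at P2 ranged over -1.52 to -1.34 in Leydig, -1.68 to -1.26 in endothelial, -1.75 to -0.454 in epithelial cells and -2.20 to -0.944 in neutrophils, and at P7 over -0.121 to 0.126 in Sertoli, -1.17 to 0.128 in epithelial, -0.798 to 0.112 in lymphoid cells, -0.132 to 0.583 in macrophages and -3.40 to -2.64 in neutrophils. Lists that turned direction in a left-out library, with their lowest and highest adjusted p, were G2/M in Sertoli cells at P2 (1.53e-06 to 0.882) and in endothelial cells at P7 (1.22e-10 to 0.77), and immediate early (2.2e-10 to 0.812, with the turn at 0.00424) and heat shock genes (7.68e-05 to 0.715) in epithelial cells at P2, all without P2 replicate 1. Without P7 replicate 1 these were ribosomal proteins in endothelial (4.39e-38 to 0.248) and mesenchymal cells (3.87e-27 to 0.879) and oxidative phosphorylation in mesenchymal cells (6.43e-22 to 0.753) at P7, and without P7 replicate 2 oxidative phosphorylation in macrophages at P7 (1.13e-05 to 0.808). With no filter on low counts the genes called were 939 and 860 in Leydig, 249 and 141 in endothelial, 18 and 132 in epithelial cells, 177 and 286 in macrophages, 1308 and 2034 in mesenchymal cells, 58 and 156 in pericytes, and 1710 in Sertoli cells at P2. With up to 20% mitochondrial UMIs they were 1146 and 1156 in Leydig cells, whose share changed by -0.709 and -0.497 (the latter against 0.378, a turn of direction in a change called in neither), with 1 class changed in each step, no value for the neutrophils, whose cluster stayed unnamed, and Cdc20 at -0.37 in Leydig cells at P7. With sums thinned to the smallest total they were 1988 and 1510 in germ cells, 37 and 18 in endothelial cells, 382 in Leydig cells at P2 and 82 in macrophages at P7, and Irf1 was at -0.035 in germ cells at P7. With only the 4 libraries of the step they were 23 and 32 in pericytes, 137 in endothelial cells and 156 in macrophages at P2, and 247 in Leydig and 27 in epithelial cells at P7. With unnamed clusters nearest to germ cells counted as germ cells the germ share changed by 1.24, now called, and 2.40. The replicate numbers were not taken as pairs, as the labels do not say what a number shares. Between E18.5 and P2, deviations of libraries with the same number had r from 0.041 to 0.345 over the 8 classes. Mesenchymal (0.345) and Sertoli cells (0.304) had the highest r, and r with P7 was from -0.095 to 0.06. Something shared by number between E18.5 and P2 is thus not excluded. With a replicate block the genes called were 157 and 68 in endothelial cells and 17 and 45 in pericytes, and the share changed by -0.985 in epithelial cells at P2, now called, and by -0.002 in Sertoli cells at P7. The DESeq2 Wald test called 37 and 80 in macrophages, 641 in mesenchymal cells at P2 and 23 in pericytes at P7. Leiden resolution 2 gave 42 in macrophages at P2. Doublet calls kept gave 9 in pericytes at P2, a share change of -0.02 in Sertoli cells at P7 and Cdh1 at -0.103 in germ cells at P2. Genes at 0.1 of the highest class mean or above gave 3 and 9 in pericytes. Without the clusters led by Acta2 or Myh11, Eln was at -0.411, Rbp4 at -0.071 and Tagln at -1.44 in mesenchymal cells at P7. With an estimated correlation 1 list was called in Leydig cells at P2 and 0 in every other class and step. With no block the germ against Sertoli difference was called for 2179 and 4141 genes, and for 27 cell cycle genes as higher in germ cells at P2. Thinned to 4000 UMIs, cells with a Mki67 UMI were 8.12%, 11.6% and 23.21% of germ, 24.28%, 21% and 13.97% of Sertoli and 19.17%, 13.3% and 9.51% of mesenchymal cells over the 3 ages, and 4.01% of Leydig cells at P2. Germ cells with a UMI were then 47.36%, 11.32% and 0.45% for Dnmt3l, 39.23%, 7.64% and 3.08% for Piwil4, 3.36%, 35.8% and 17.48% for Id4, 8.6%, 11.26% and 26.33% for Sox3, 37.76%, 39.04% and 33.4% for Pou5f1 and 0%, 0.72% and 3.36% for Neurog3. At P2 and P7 they were 24.93% and 12.66% for Gfra1, 23.59% and 8.94% for Etv5, 4.52% and 8.8% for Kit and 1.9% and 1.12% for Eomes, at E18.5 and P7 0% and 2.83% for Nanos2, and at P7 36.18% for Stra8. With no thinning, cells with a Mki67 UMI were 15.72%, 25.16% and 55.58% of germ, 35.46%, 30.04% and 22.26% of Sertoli, 24.54%, 17.8% and 10.46% of mesenchymal and 12.5%, 5.28% and 11.17% of Leydig cells. Germ cells with a UMI were then 79.02%, 29.58% and 3.16% for Dnmt3l, 63.5%, 22.51% and 13.01% for Piwil4, 11.76%, 66.24% and 44% for Id4, 3.57%, 48.67% and 27.75% for Etv5, 15.32%, 28.49% and 64.85% for Sox3, 81.4%, 66.95% and 59.44% for Pou5f1, 5.41%, 40.89% and 57.11% for Stra8, 14.14%, 13.2% and 25.61% for Kit, 0.44%, 1.47% and 11.79% for Neurog3 and 0.44%, 3.75% and 10.96% for Nanos2, and at P2 and P7 41.69% and 32.44% for Gfra1 and 5.27% and 3.8% for Eomes.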

Other observations

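RNA of the cold-inducible RNA-binding protein gene Cirbp was higher at P2 than at E18.5 in most of the testis. It rose in germ cells (3.32), endothelial cells (1.64), pericytes with vascular smooth muscle (1.33), Leydig cells (1.32), mesenchymal cells (1.29) and Sertoli cells (0.88), and was not called in macrophages (0.87) or epithelial or mesothelial cells (0.86). Rbm3, a second gene that mild cold induces, rose in germ (1.85) and Sertoli cells (1.40), and also in Leydig cells. It was not called in endothelial (0.51), mesenchymal (0.64), epithelial or mesothelial cells (1.02), macrophages (0.72) or pericytes (0.75). From P2 to P7 Cirbp rose again in germ cells (1.76, adjusted p = 2.41e-06), and neither gene was otherwise called. Both genes were picked after their values were seen in some classes. Cirbp was among the largest germ rises and Rbm3 among the largest Sertoli rises. No temperature was given in the sources used here.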
